A study of Mus musculus with 4 samples.

How the data were processed

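RNA from mouse 4T1-T breast cancer cells, in which the asparagine synthetase gene Asns had been silenced, was sequenced after growth in DMEM without or with asparagine. Each condition was represented by 2 libraries, named A and B in the labels. Per the labels' protocols, total RNA was purified with a Qiagen RNeasy kit and amplified with the NuGEN Ovation RNAseq V2 kit. Reads were processed with Bowtie2 and HTSeq on genome build mm10, per the submitters' processing notes. Program versions, settings, the gene annotation and the use of strand are not given in the sources used here. The deposited values were whole-number counts of reads per gene symbol, not normalised, in 1 table with a column for each library. Columns were assigned to samples by the sample descriptions in the labels. The table held 23481 genes and 5 HTSeq summary rows. The summary rows took between 60.1% and 70.0% of all reads in a library and were kept out of library sizes and tests. HTSeq listed 0 reads in its rows for low alignment quality and for alignments that were not unique, in every library.

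Bowtie2 does not split reads across introns by itself, so reads over exon junctions may be under-counted where no transcript index was used, and this would affect genes with many short exons most. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. For the same reason, reads that HTSeq placed outside annotated features may include reads over genes that were taken as the other strand. With no reads listed as non-unique, reads shared by near-identical gene copies may have been assigned to 1 copy. Amplification from total RNA also carries ribosomal and unprocessed RNA into the counts. The libraries held no molecular identifiers in the labels, so intervals for shares of reads cover counting error only.

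From the deposited counts, genes were kept when filterByExpr (minimum count 10, minimum total count 15) passed them, which left 12843 genes. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test on the 2 groups, with no term for the letter, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes were coded as without minus with asparagine on the log2 scale, with a prior count of 2 for log2 CPM values. The SE given with an edgeR fold change was worked back from the test, as its size divided by the square root of F. It rests on a variance shared by both groups. CPM values were scaled to the TMM-adjusted total of gene counts unless stated otherwise. The common biological coefficient of variation was 11.2%. Nothing in the labels says that libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical.

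Before the data were examined, 26 gene lists of pathways, complexes, cell states and other cell types were written from textbook knowledge, together with the tests, the alternatives and the rule for naming genes. Of the 658 symbols in the lists, 641 were found in the table. The 13 mitochondrially encoded genes were not analysed here. Lists with at least 5 tested members, 23 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Members called in the edgeR test were counted beside each list, adjusted over all genes and again adjusted over the list alone. Besides Asns, the genes named are the 6 with the largest and the 6 with the smallest log2 fold change among called genes with a mean of at least 5 CPM and with both libraries of a group above both of the other, gene models with Gm or Rik names or names like those of pseudogenes being passed over. Up to 2 called members with the largest change were named from each list, or the member with the smallest p where none was called. Any other gene named was chosen after its values were seen. Some genes that met the rule are not reported here.

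Alternatives were the size factors of DESeq2 within edgeR, upper quartile scaling, the DESeq2 Wald test, limma-voom, no low-count filter, a filter of 5 CPM in 2 libraries, the letter as a block, each library left out in turn, the 10 most abundant genes left out, camera with an estimated correlation, and fry. With a library left out, its group had a single library, which was assumed to vary like the other group. Camera with an estimated correlation also rests on the 2 residual degrees of freedom. A call lost under it therefore does not show that correlated genes had given the call. The pipeline was tested on simulated data, with counts drawn for the same 12843 genes and 2 libraries against 2. The edgeR test recovered 43.3% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 98.5% of those changed 4-fold, and 4 of its 152 calls were false. The simulation gave both groups the same spread and set no library apart. In the data the spread was unequal between the groups, so these rates may not hold for this comparison. With 2 libraries in each group, no other splits of the samples and no outlier test could be used.

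Gene positions are those of RefSeq on GRCm38.p6, which has the same coordinates as mm10. Transcript length, GC content, asparagine codons, gene nesting and exon overlaps were taken from GENCODE M21, and 94.2% of tested genes had a length and GC content. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.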

Results

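The transcriptome of 4T1-T cells, a derivative of the mouse mammary carcinoma line 4T1, was profiled by RNA sequencing after silencing of Asns, which encodes the enzyme that makes asparagine from aspartate. The design asked how the presence of asparagine in the culture medium changed gene expression in these cells. There were 2 libraries from cells grown without asparagine and 2 from cells grown with it. Counts assigned to genes were 17977552 in library A and 22581543 in library B without asparagine, and 23867011 in library A and 30260582 in library B with asparagine. The libraries without asparagine differed more from each other than those with it. Across genes, library B without asparagine had Spearman correlations of 0.992 and 0.993 with libraries A and B with asparagine, closer than with library A of its own group (0.991), and library A had 0.985 with each library with asparagine. In library A without asparagine HTSeq placed 56.6% of all reads outside annotated features, against 47.4% in library B without asparagine and 49.3% and 46.3% in the libraries with asparagine. Rn45s, the ribosomal RNA precursor, took 3.53% of its gene counts, against 1.66%, 0.884% and 1.18% in the same order. The widest 95% Wilson interval of these shares spanned 0.0258 percentage points and covered counting error only. The chi-square statistic per degree of freedom between libraries of a group was 44.8 without and 5.28 with asparagine, so no library was a copy of another.

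**Figure D1:**
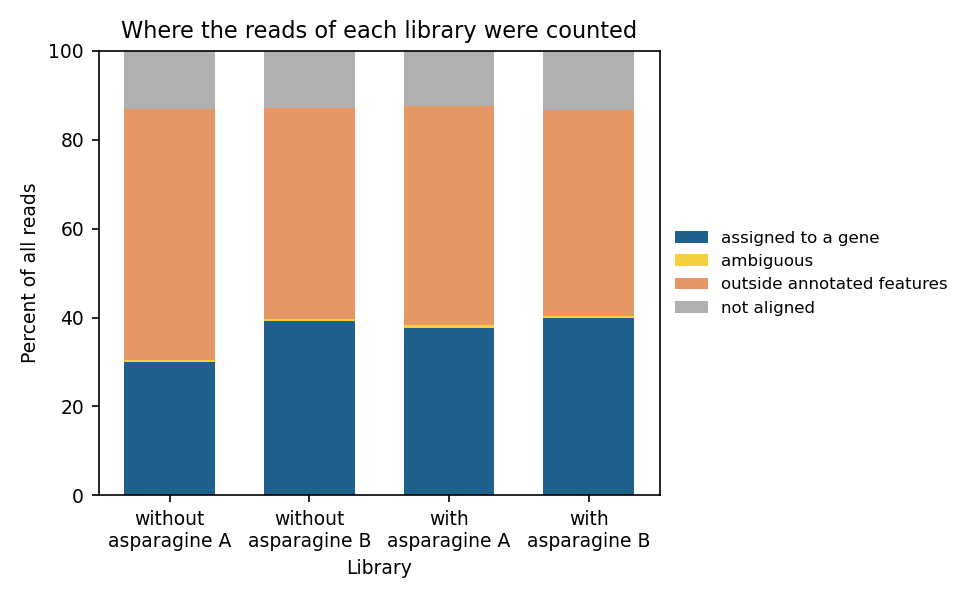
Share of all reads (percent, y axis) that were assigned to a gene, ambiguous, outside annotated features or not aligned, for each of the 4 libraries (x axis). In library A without asparagine HTSeq placed 56.6% of reads outside annotated features, more than the 46.3% to 49.3% of the other libraries.

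Asns transcript was present in every library. Its level was 75.0 and 89.2 CPM in libraries A and B without asparagine and 103 and 101 CPM in libraries A and B with it. The means were 82.1 ± 10.1 CPM (SD, n = 2) and 102 ± 0.990 CPM (SD, n = 2), a log2 fold change of -0.31 ± 0.12 (SE) that did not pass the edgeR test (adjusted p = 0.235). Without library A the log2 fold change was -0.19 (adjusted p = 0.0928), and without library B of the same group it was -0.45 and was called (adjusted p = 1.52e-06). The gene lies on chromosome 6 from 7675165 to 7693209. No unsilenced library was analysed here, so the values do not measure the silencing.

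Growth without asparagine changed 237 of the 12843 genes tested, 99 of them higher and 138 lower (edgeR quasi-likelihood test, adjusted p threshold 0.05). Changes of more than 2-fold were found for 65 of the higher and 60 of the lower genes. Among the strongest increases were Krt14, the keratin of basal epithelial cells, and the secreted ligand Wnt7a. Among the strongest decreases were Add2, which encodes beta-adducin of the membrane skeleton, the peptide hormone gene Cck, and Lgr6, a receptor for R-spondins. Leaving out a library without asparagine gave 910 higher and 1141 lower genes for library A and 2502 and 2861 for library B. Leaving out a library with asparagine gave 28 and 30 for library A and 24 and 24 for library B.

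Among genes that met the naming rule, AU018091 had the largest increase. It rose from 1.42 ± 0.164 CPM with asparagine to 10.7 ± 2.89 CPM without it (SD, n = 2 each). The log2 fold change was 2.90 ± 0.26 (SE, adjusted p = 0.00678). Krt14 rose from 4.48 ± 0.691 CPM to 32.6 and 27.4 CPM in libraries A and B, a log2 fold change of 2.73 ± 0.17 (adjusted p = 0.00434). Prl2c2, a proliferin of the prolactin family, rose 4.83-fold to 58.6 ± 2.60 CPM (adjusted p = 0.00270), but it has near-identical neighbouring copies and its own share of these reads is uncertain. Wnt7a rose 4.37-fold to 12.2 ± 3.03 CPM (adjusted p = 0.0104). Gpr97, an adhesion G protein-coupled receptor gene now named Adgrg3, rose 4.31-fold to 17.6 ± 0.536 CPM (adjusted p = 0.00434). AU018091 lies on chromosome 7 from 3154658 to 3169203 and Krt14 on chromosome 11 from 100203162 to 100207510. Wnt7a lies on chromosome 6 from 91363981 to 91411353. Prl2c2 lies on chromosome 13 from 12996120 to 13005393 and Gpr97 on chromosome 8 from 95017113 to 95045250.

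Add2 fell from 11.1 ± 1.75 CPM with asparagine to 1.08 ± 0.0584 CPM without it (SD, n = 2 each), a log2 fold change of -3.35 ± 0.23 (SE, adjusted p = 0.00434). Cck fell from 14.5 ± 1.59 to 2.79 ± 0.550 CPM, a log2 fold change of -2.37 ± 0.20 (adjusted p = 0.00572). Lgr6 fell from 83.4 ± 2.57 CPM to 19.1 and 24.8 CPM in libraries A and B (log2 fold change -1.92, adjusted p = 0.00473). Adamts9, a secreted metalloprotease, fell from 12.8 ± 0.923 to 3.76 ± 1.77 CPM (log2 fold change -1.74, adjusted p = 0.0368), a call that was lost without library B with asparagine (log2 fold change -1.68 ± 0.35, against -1.74 ± 0.28 with all libraries, adjusted p = 0.0850). Synpo, which encodes the actin-associated protein synaptopodin, fell from 65.9 ± 4.17 to 19.7 ± 2.43 CPM (log2 fold change -1.74, adjusted p = 0.00473). Mmp3, the matrix metalloprotease stromelysin-1, fell from 93.2 ± 4.71 to 29.0 ± 1.71 CPM (log2 fold change -1.69, adjusted p = 0.00434). Add2 lies on chromosome 6 from 86028681 to 86124409 and Adamts9 on the same chromosome from 92772699 to 92944450. Cck and Mmp3 lie on chromosome 9, from 121489824 to 121495694 and from 7445822 to 7455975. Lgr6 lies on chromosome 1 from 134983300 to 135105374 and Synpo on chromosome 18 from 60593981 to 60660173. In GENCODE M21, exons of Add2 and Adamts9 overlap exons of genes on the opposite strand, so reads of those genes could be included in their counts. The same holds for Aldh1l2, Bnip3, Car9, Ctgf, Cxcl16, Dsp, Gins2, Il1a, Pdgfra, Psmb8, Tgfb2 and Tnfaip2 among the genes named further on. Overlaps were looked up only for genes given by the naming rule and for called list members. Cdh1, Vim, Il33, Ldha, Postn and Col1a1 were not looked up, nor were genes first named under Other observations. Cyr61 was looked up under this older symbol only. Exons of Nme1 overlap those of another gene on the same strand.

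**Figure D2:**
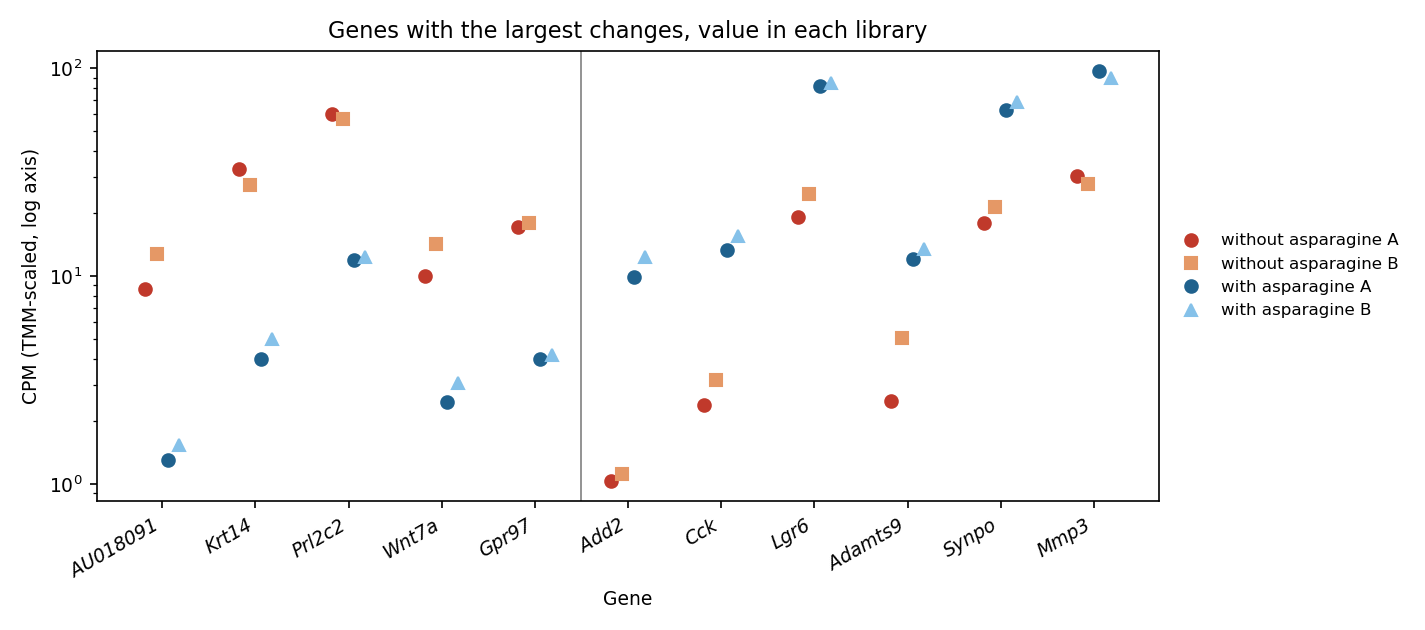
CPM (TMM-scaled, log axis) of 5 of the 6 genes with the largest increase (left of the line) and the 6 with the largest decrease (right) without asparagine, with each library as a point. The ranking is among genes that met the naming rule, including a mean of at least 5 CPM. For every gene shown, both libraries of a group lay on the same side of both libraries of the other, as the naming rule required (Krt14 at 27.4 and 32.6 CPM without and 3.99 and 4.97 CPM with asparagine).

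Epithelial genes were higher without asparagine. Of 25 members tested, 21 had a positive fold change, and 4 passed the edgeR test, all of them higher, or 14 adjusted over the list alone. The list median was 0.51 on the log2 scale, and camera called the list higher (adjusted p = 2.03e-08), though not with an estimated correlation (adjusted p = 0.578). Besides Krt14, Esrp1, an epithelial splicing regulator, rose 2.58-fold from 6.68 ± 0.413 to 17.2 ± 2.54 CPM (adjusted p = 0.0138). The Esrp1 call was lost without either library with asparagine, where the log2 fold change was 1.30 ± 0.27 without A and 1.43 ± 0.27 without B (SE, adjusted p = 0.0577 and 0.0505) against 1.37 ± 0.16 with all libraries. The other 2 called members, named after their values were seen, were the desmosome gene Dsp (log2 fold change 0.82, adjusted p = 0.0145) and the adhesion gene Epcam (0.68, adjusted p = 0.0368). Cdh1, which encodes E-cadherin and was also chosen after its values were seen, had 381 ± 45.8 CPM without and 269 ± 11.1 CPM with asparagine (log2 fold change 0.50, adjusted p = 0.106).

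Mesenchymal and EMT genes (epithelial-mesenchymal transition) were not called as a list. Their median was 0.11 (camera adjusted p = 0.195), or 0.04 without library A and 0.17 without library B with asparagine, with 5 of 33 tested members higher and 1 lower, or 6 and 3 adjusted over the list alone. Ctgf, a secreted matricellular protein gene now named Ccn2, rose 2.99-fold from 26.2 ± 2.94 to 78.6 ± 5.98 CPM (adjusted p = 0.00511), and Mmp3 was the member that fell. Among the other higher members were Cyr61, Mmp9 and Tgfb2, named after their values were seen, with log2 fold changes of 1.17, 1.21 and 0.81. Vim, which encodes the mesenchymal filament protein vimentin and was chosen in the same way, had 3061 ± 227 CPM without and 3034 ± 87.3 CPM with asparagine (adjusted p = 0.962).

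Inflammatory cytokines and targets of the transcription factor NF-kB were higher without asparagine, with a median of 0.53 (camera adjusted p = 4.18e-05, and 0.578 as the adjusted p with an estimated correlation). Of 23 tested members 7 rose and 1 fell, or 12 and 2 adjusted over the list alone. Il1a, which encodes interleukin-1 alpha, rose 5.98-fold from 0.666 ± 0.0496 to 4.03 ± 0.388 CPM (adjusted p = 0.00831). Cxcl1, a chemokine that attracts neutrophils, rose 3.82-fold from 14.6 ± 0.866 to 55.8 ± 18.1 CPM (adjusted p = 0.0121). Cxcl5, C3, Cxcl16, Ptgs2 and Ccl2, named after their values were seen, rose by 1.36, 1.23, 1.07, 0.74 and 0.72 on the log2 scale. Tnfaip2 and Il33, chosen in the same way, had log2 fold changes of -0.84 and -1.85 (edgeR adjusted p = 0.0315 and 0.0720). Of the tested members, 18 had a fold change above 0 and 5 below. Without library A of the cells without asparagine, which had the largest share of reads outside annotated features, the list median was 0.35 (camera adjusted p = 7.475e-04).

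The ATF4 and CHOP list, genes of the amino acid and integrated stress response, was called higher with a median of 0.23 (camera adjusted p = 0.0262, and 0.578 as the adjusted p with an estimated correlation). None of its 19 tested members passed the edgeR test over all genes, and 6 were higher adjusted over the list alone. Atf3, a stress-induced transcription factor gene, had 6.76 ± 1.07 CPM without and 3.36 ± 0.0582 CPM with asparagine (log2 fold change 1.01, adjusted p = 0.0638). The list call was lost without library B without asparagine (median 0.21, adjusted p = 0.212) and with the filter of 5 CPM in 2 libraries (median 0.20, adjusted p = 0.0849).

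Other lists of amino acid metabolism were not called. Serine, one-carbon and non-essential amino acid synthesis had a median of 0.01 (camera adjusted p = 0.663), with 1 of 20 tested members higher over all genes and 1 adjusted over the list alone. That member, the mitochondrial folate enzyme gene Aldh1l2, rose 2.03-fold from 9.64 ± 0.378 to 19.7 ± 3.82 CPM (adjusted p = 0.0368), a call lost without either library with asparagine (log2 fold change 0.98 ± 0.26 without A and 1.06 ± 0.27 without B, against 1.02 ± 0.17 with all, adjusted p = 0.219 and 0.182). Amino acid transporters (18 tested, median 0.11) and cytosolic aminoacyl-tRNA synthetases (20 tested, median 0.05) each had a camera adjusted p of 0.329 and 0 called members, also 0 adjusted over the list alone. The smallest p among the transporters was that of Slc3a2 (log2 fold change 0.42, adjusted p = 0.0946). Among the synthetases it was that of Farsa (0.42, adjusted p = 0.192), whose log2 fold change was 0.26 without library A without asparagine. Without library A of the cells without asparagine these 3 lists were called higher (medians 0.13, 0.16 and 0.12, adjusted p = 0.0153, 0.0135 and 0.0135), and without library B their medians were -0.12, -0.08 and -0.06. Endoplasmic reticulum chaperones had a median of -0.15 (camera adjusted p = 0.0924) with 1 of 22 members lower, or 2 adjusted over the list alone, and the median was -0.04 without library A without asparagine (adjusted p = 0.262). Xbp1, a transcription factor of the unfolded protein response, fell from 56.2 ± 2.35 to 36.9 ± 1.05 CPM (log2 fold change -0.61, adjusted p = 0.0424). The Xbp1 call was lost with upper quartile scaling (log2 fold change -0.56 ± 0.11, adjusted p = 0.0632) and without either library with asparagine (-0.65 ± 0.21 without A and -0.57 ± 0.21 without B, against -0.61 ± 0.11 with all, adjusted p = 0.446 and 0.607).

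Genes of ribosome production were higher without asparagine. Ribosome biogenesis and MYC-linked nucleolar genes had a median of 0.27 (camera adjusted p = 1.58e-06, and 0.578 as the adjusted p with an estimated correlation), with 27 of 30 members above 0. None passed the edgeR test over all genes and 12 were higher adjusted over the list alone. Rrp12, a ribosome assembly factor gene, had 49.6 ± 8.19 CPM without and 31.4 ± 0.0497 CPM with asparagine (adjusted p = 0.0746). Ribosomal protein genes had a median of 0.29 (camera adjusted p = 5.57e-05, and 0.613 as the adjusted p with an estimated correlation), with 34 of 41 members above 0. No member was called, over all genes or adjusted over the list alone, and Rpl37 had the smallest p (log2 fold change 0.65, adjusted p = 0.140). Rpl37 had 187 and 132 CPM in libraries A and B without asparagine and 94.4 and 110 CPM with it. Its log2 fold change was 0.37 without library A without asparagine. Across genes, the fold change had a Spearman correlation of -0.214 with transcript length, and the median length was 1020 bases for the ribosomal protein genes against 3054 for all tested genes with a length. In a check chosen after these values were seen, the ribosomal protein median lay above all of 10000 random lists of other genes matched in broad classes of GC content, length and expression, whose median was 0.05. The random lists drew genes independently, while the estimated correlation of this list was 0.36, so their spread may be too narrow. In the same check the histone list lay at percentile 99.84, though its median was -0.03 without library A without asparagine. The ribosomal protein median was 0.17 without library A without asparagine (adjusted p = 6.191e-04) and 0.19 without library A with asparagine (0.0281).

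Replication-dependent histones and nuclear non-coding RNA had a median of 0.29 (camera adjusted p = 0.00236, and 0.652 as the adjusted p with an estimated correlation), with 23 of 24 members above 0 and 0 called, also 0 adjusted over the list alone. Rn45s had 34620 and 16790 CPM in libraries A and B without asparagine and 8868 and 11910 CPM with it (log2 fold change 1.31, adjusted p = 0.118). The list call was lost without library A without asparagine (median -0.03, adjusted p = 0.385) and without library A with asparagine (median 0.12, adjusted p = 0.140). Without library B without asparagine the median was 0.48 (adjusted p = 8.17e-05).

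Glycolysis and hypoxia genes were lower without asparagine. The median was -0.34 (camera adjusted p = 7.55e-04, and 0.613 as the adjusted p with an estimated correlation), with 22 of 28 members below 0 and 3 called lower, or 7 adjusted over the list alone. Egln3, a prolyl hydroxylase that marks hypoxia-inducible factor for degradation, fell from 151 ± 3.99 to 69.9 ± 19.8 CPM (log2 fold change -1.11, adjusted p = 0.0379). Car9, which encodes carbonic anhydrase 9, fell from 59.5 ± 3.00 to 32.0 ± 4.72 CPM (log2 fold change -0.90, adjusted p = 0.0280). The third, Bnip3, a mitophagy receptor gene named after its values were seen, had a log2 fold change of -0.75 (adjusted p = 0.0368). Both the Egln3 and Car9 calls were lost without either library with asparagine. The log2 fold change of Egln3 was -1.08 ± 0.25 without A and -1.14 ± 0.25 without B (adjusted p = 0.114 and 0.105), against an SE of 0.19 with all libraries, and that of Car9 -0.95 ± 0.22 and -0.85 ± 0.22 (0.115 and 0.201), against an SE of 0.13. Ldha, the lactate dehydrogenase gene, chosen after its values were seen, had 1335 and 2938 CPM in libraries A and B without asparagine and 3015 and 3041 CPM with it. Without library A without asparagine, the list median was -0.12 and the list was still called (adjusted p = 0.0244).

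Cholesterol biosynthesis genes and SREBP2 targets were lower as a list (median -0.21, camera adjusted p = 8.321e-04, and 0.613 as the adjusted p with an estimated correlation), with 21 of 25 members below 0. None passed the edgeR test over all genes and 6 were lower adjusted over the list alone. Pmvk, a kinase gene of the mevalonate pathway, had 19.2 ± 1.81 CPM without and 29.0 ± 0.336 CPM with asparagine (adjusted p = 0.0738). The median was -0.09 without library A without asparagine (adjusted p = 0.0161) and -0.38 without library B (2.945e-04). Nuclear-encoded oxidative phosphorylation (34 tested, median 0.11, camera adjusted p = 0.0874) and nucleotide synthesis (21 tested, median 0.06, adjusted p = 0.573) were not called and had 0 called members, also 0 adjusted over the list alone. The smallest p in these lists were those of Uqcrq (log2 fold change 0.71, adjusted p = 0.108) and Nme1 (0.46, adjusted p = 0.0926). Both lists were called higher without library A without asparagine (adjusted p = 0.0161 and 0.0244), oxidative phosphorylation also with no low-count filter (adjusted p = 0.0160), and the nucleotide synthesis median was -0.04 without library B. NRF2 and oxidative stress genes (24 tested, median -0.07, camera adjusted p = 0.176) had 0 called members, or 5 lower adjusted over the list alone, and Gsr had the smallest p (log2 fold change -0.48, adjusted p = 0.0843). Their median was -0.02 without library A and -0.12 without library B without asparagine. Autophagy and lysosome genes (28 tested, median -0.10, camera adjusted p = 0.0874) had 0 called members, also 0 adjusted over the list alone. Their smallest p was that of Nbr1 (log2 fold change -0.43, adjusted p = 0.0958), and the list was called lower without library B without asparagine (median -0.15, adjusted p = 0.0273) but had a median of -0.01 without library A (adjusted p = 0.454) and -0.07 without library B with asparagine (0.142).

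Interferon response genes were called lower (median -0.22, camera adjusted p = 0.0422, and 0.578 as the adjusted p with an estimated correlation), with 15 of 27 members below 0. None passed the edgeR test over all genes and 2 were lower adjusted over the list alone, and Psmb8, an immunoproteasome subunit gene, had 10.6 ± 1.17 CPM without and 17.2 ± 0.718 CPM with asparagine (adjusted p = 0.0684). The list call was lost without library A (median -0.18, adjusted p = 0.135) or B (-0.30, 0.193) without asparagine, without library B with asparagine (-0.15, 0.0684) and with the filter of 5 CPM (-0.16, 0.298). With no filter it was also lost, and the median turned to 0.03 while camera still pointed down (adjusted p = 0.399). Without library A with asparagine the list was still called, with a median of -0.05 (adjusted p = 0.0356).

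The p53 target list was not called by camera (median 0.07, adjusted p = 0.0874), but 3 of 15 tested members rose, or 4 adjusted over the list alone. Fold changes were above 0 for 8 members and below 0 for 7. The list was called higher without library A without asparagine (median 0.07, adjusted p = 0.0339), with no filter (median 0.07, adjusted p = 0.0184) and by fry (adjusted p = 0.00412), but not with an estimated correlation (adjusted p = 0.607), and its median was 0.04 without library B with asparagine. Fas, a death receptor gene, rose 3.83-fold from 0.955 ± 0.313 to 3.63 ± 0.192 CPM (adjusted p = 0.0316), a call lost without either library with asparagine (log2 fold change 2.29 ± 0.46 without A and 1.61 ± 0.43 without B, against 1.94 ± 0.30 with all, adjusted p = 0.0566 and 0.222). Plk2, a stress-responsive kinase gene, rose 3.63-fold from 31.9 ± 2.28 to 116 ± 14.4 CPM (adjusted p = 0.00434). Perp, a desmosome-associated gene named after its values were seen, rose by 0.87 on the log2 scale (adjusted p = 0.0144). Immediate early genes had a median of 0.03 and a mean of -0.02 and camera pointed down (adjusted p = 0.753), with 1 of 25 members lower, or 3 higher and 5 lower adjusted over the list alone. Dusp6, a phosphatase that acts on ERK, fell from 134 ± 6.27 to 86.9 ± 2.87 CPM (log2 fold change -0.63, adjusted p = 0.0368), a call lost without either library with asparagine (-0.68 ± 0.22 without A and -0.58 ± 0.21 without B, against an SE of 0.10 with all, adjusted p = 0.412 and 0.599).

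Cell cycle lists were not called. DNA replication and S phase genes had a median of 0.04 over 32 members (camera adjusted p = 0.561) and mitosis and G2/M genes -0.04 over 30 (0.454), with 0 called members in each, also 0 adjusted over the list alone. The first median was 0.01 without library A with asparagine, and the second was 0.01 with upper quartile scaling. The smallest p were those of Gins2 (log2 fold change -0.57, adjusted p = 0.247) and Ccnb2 (-0.39, adjusted p = 0.144). Gins2 had 30.6 and 52.1 CPM in libraries A and B without asparagine and 61.4 and 62.1 CPM with it. Its log2 fold change was -0.25 without library A without asparagine.

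Among markers of other cell types, 2 of 12 fibroblast genes were tested, too few for a list test, and adjusted over the list alone 1 was higher and 1 lower. Pdgfra, a growth factor receptor gene, fell from 41.7 ± 1.48 to 20.5 ± 3.33 CPM (log2 fold change -1.03, adjusted p = 0.0221), a call lost without either library with asparagine (-0.99 ± 0.23 without A and -1.07 ± 0.23 without B, against an SE of 0.14 with all, adjusted p = 0.114 and 0.0943). Postn, chosen after its values were seen, had 0.943 ± 0.131 CPM without and 0.163 ± 0.0524 CPM with asparagine (adjusted p = 0.0609). The collagen gene Col1a1, also chosen in this way, lay between 0.165 and 0.419 CPM in the 4 libraries, here computed without TMM scaling. Of 16 leukocyte markers 3 were tested and 0 were called, also 0 adjusted over the list alone, and Cd68 had 6.79 ± 0.182 CPM without and 5.77 ± 0.228 CPM with asparagine (adjusted p = 0.471). Endothelial markers (6 tested, median -0.29, camera adjusted p = 0.363) had 0 called members, also 0 adjusted over the list alone, and Flt1 had 45.5 ± 0.819 and 55.9 ± 2.97 CPM (adjusted p = 0.211). Their median was -0.02 without library B without asparagine and -0.07 without library B with it.

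**Figure D3:**
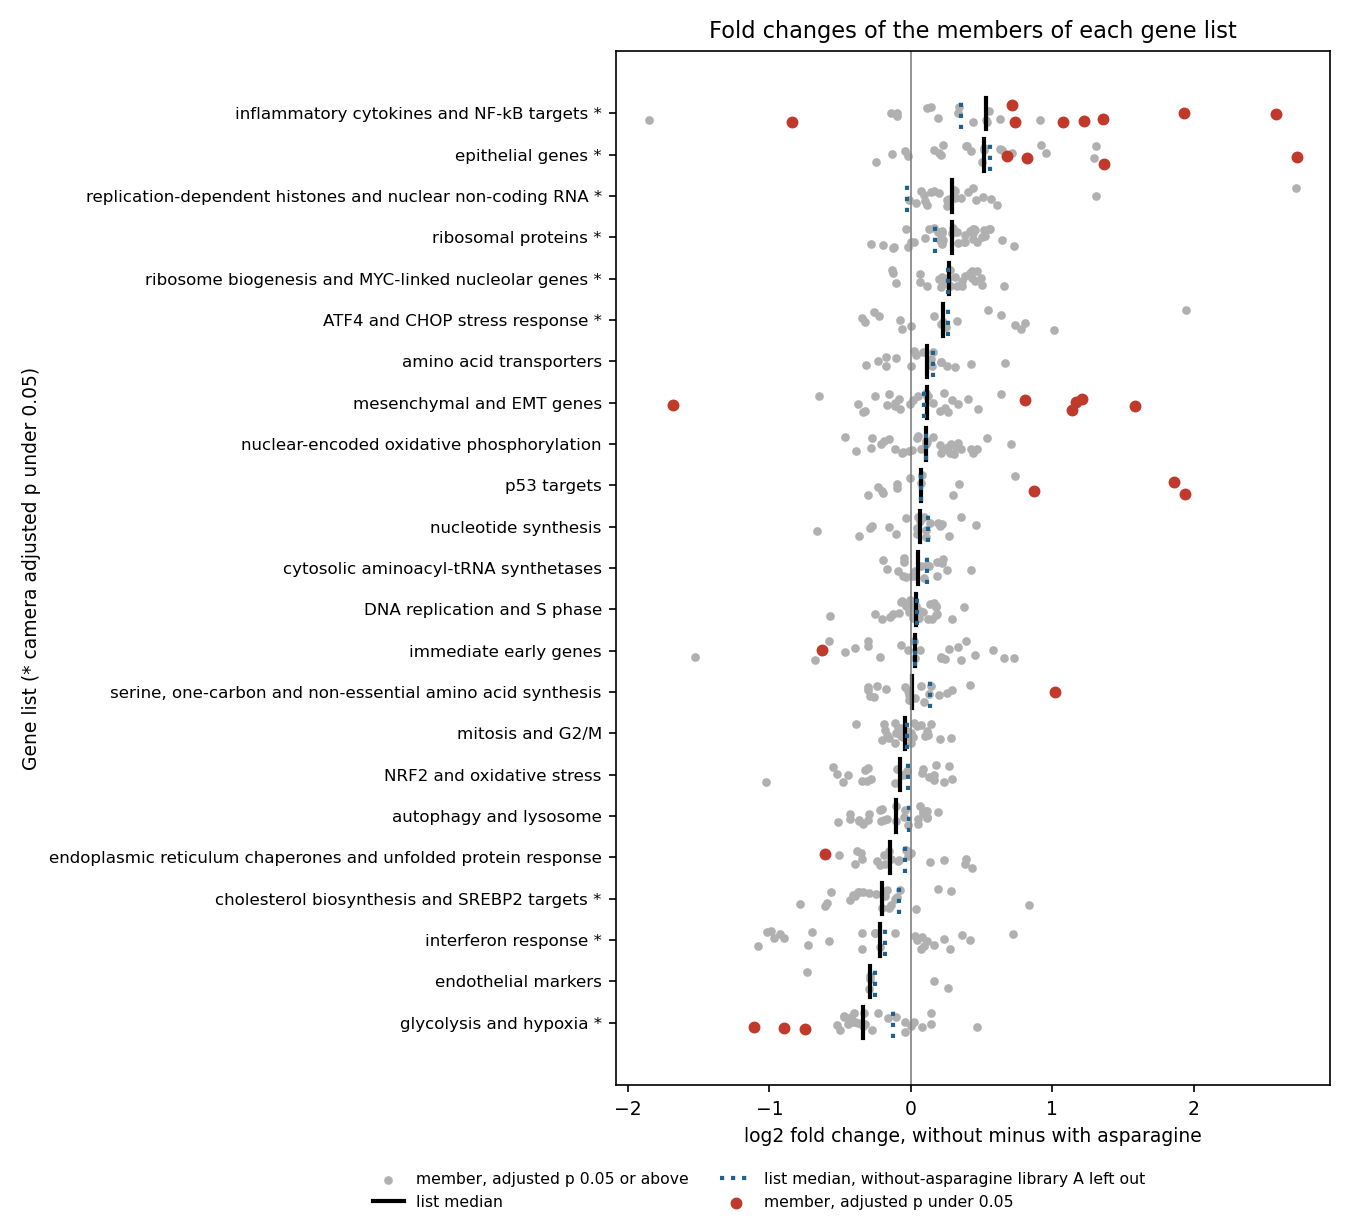
Log2 fold change, without minus with asparagine (x axis), of each tested member (points) of the 23 gene lists tested (y axis), with members at an adjusted p under 0.05 in red, the list median as a black line and the median without library A of the cells without asparagine as a dotted line. Epithelial genes lay at a median of 0.51 with all libraries and 0.56 without library A, and glycolysis and hypoxia genes at -0.34 and -0.12.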

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

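The tests of transcript length and of receptor genes against library B without asparagine were chosen after the result was seen, and the other tests in this part before. Reads that HTSeq placed outside annotated features, which no comparison used, made up 56.57% of all reads in library A without asparagine, above both libraries with asparagine (49.3% and 46.31%). Library B of the same group had 47.38%.

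Technical explanations for why library A stands apart were tested, and no biological explanation was, since no group in the design separates it from library B. Genomic DNA was argued against as what sets library A apart from all other libraries, because 1450 olfactory and vomeronasal receptor genes took 577 of 59956962 reads in library A, a share 0.7033 times that of the highest other library, library B with asparagine (1038 of 75855285 reads), and their exact 95% Poisson intervals did not overlap. Against library B without asparagine (373 of 57632726 reads) the share was 1.487 times as high, also with intervals that did not overlap, so genomic DNA stays open for part of the difference between these libraries. A trend with transcript length was weak, with a Spearman correlation of -0.1613 across genes, which are not independent replicates, with the log2 ratio of library A to B. More unprocessed RNA in library A stays open as a candidate explanation: 376 genes lying inside introns of other genes were higher in A than in B by a median of 0.121 on the log2 scale relative to 11719 other genes (permutation p = 1e-05, the smallest that 100000 permutations can give, across genes), against 0.00693 for library B relative to the mean with asparagine. For library A relative to B with asparagine the figure was 0.0303. The 376 genes were not matched to the others on transcript length, so the length trend is not separated from this shift.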

How the results depend on the processing

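All alternatives here were fixed before the data were examined. In each of the 237 called genes both libraries of one group lay beyond both of the other, so leaving out a library could not turn its sign, and every one that an alternative tested also kept it under the 8 settings that left out no library. The counts of higher and lower genes lay within 1.5 times the main counts under DESeq2 size factors (98 and 135), upper quartile scaling (107 and 113), limma-voom (98 and 137), the filter of 5 CPM (71 and 116) and without the 10 most abundant genes (100 and 137). They were 170 and 259 with the DESeq2 Wald test and 615 and 719 with no filter, which tested 19828 genes. With no filter edgeR's prior degrees of freedom, the weight of the common trend over a gene's own variance, were infinite. They were 4.963 in the main test and 21.24 with the letter as a block. The common coefficient of variation was 11.36% with no filter, against 11.24%. The cause of the higher counts was not tested. Leaving out each library in turn gave 24 to 2502 higher and 24 to 2861 lower genes. The low counts came with a common coefficient of variation of 15.6%, set by the pair without asparagine, and the high ones with 4.60%, set by the pair with it. Asns ranged from -0.4465 to -0.1945 in log2 fold change when each library was left out, and was called without library B without asparagine (-0.4465). Nothing in the labels says that a shared letter pairs libraries, and the deviations of same-letter libraries from their group means correlated at 0.123, which with 2 pairs does not settle it, so the letters were used as names. With the letter as a replicate block 344 genes were higher and 472 lower, Asns stayed uncalled, Atf3, Pmvk, Gins2, Nme1, Rpl37, Rrp12, Uqcrq, Psmb8, Gsr and Rn45s were called, and 6 lists were higher and 3 lower as before. Leaving out each library gave 5 to 11 higher and 2 to 3 lower lists, with 11 higher without library A without asparagine. With an estimated correlation 0 lists were higher and 0 lower, where the main test called 6 and 3. That setting does not tell correlation between genes from its 2 residual degrees of freedom. The ATF4 and CHOP list had an estimated correlation of 0.0094, under the preset 0.01. Its unadjusted camera p still went from 0.0091 to 0.12. Among the other called lists, only interferon response also had an estimate under the preset (-0.033). The estimate was 0.83 for histones, 0.47 for glycolysis, and 0.36 for both ribosomal proteins and cholesterol biosynthesis. It was 0.19 for epithelial genes, 0.13 for inflammatory cytokines and 0.033 for ribosome biogenesis. For lists above the preset, the main camera p may be too small. With fry, which does not compare a list with other genes, 2 lists were higher (ribosome biogenesis, and p53 targets, which the main test did not call) and 1 lower (interferon response). The direction of the immediate early list turned with no filter (median 0.0254), with the filter of 5 CPM (0.0552), without library A without asparagine (0.0263), and without library B with asparagine (-0.0020), within medians of -0.0641 to 0.0467 over the libraries left out. Without library B without asparagine it turned for serine and one-carbon synthesis (-0.1219), transporters (-0.0845), aminoacyl-tRNA synthetases (-0.0584) and nucleotide synthesis (-0.0363), whose highest medians, without library A, were 0.1326, 0.1566, 0.1153 and 0.1237. None of the lists that turned was called under the setting that turned it, and the cause was not tested. With 2 libraries in each group, changes of 1.5-fold were recovered for 43.3% of genes simulated with equal spread in both groups. Genes not called may still differ.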

Other observations

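The tests of single libraries on the epithelial and glycolysis lists were chosen after the results were seen, the 3 wider lists after the genes that prompted them were seen, and the other tests in this part before. The genes of the next sentences were chosen after their values were seen. The laminin-332 genes Lama3 and Lamb3, which encode chains of an epithelial basement membrane protein, rose without asparagine by 1.13 and 1.33 on the log2 scale (edgeR adjusted p = 0.00799 and 0.00678). Dsg2, a desmosomal cadherin gene, rose by 1.19 (adjusted p = 0.00678). Thbs1 and Gadd45b rose by 1.02 and 1.69 (adjusted p = 0.00778 and 0.0210), beside Ctgf and Cyr61, which are known targets of the coactivator YAP. In the other direction, the fatty acid desaturase genes Scd1 and Scd2 and the isocitrate dehydrogenase gene Idh1 had log2 fold changes of -0.96, -0.84 and -1.20 (adjusted p = 0.0392, 0.0369 and 0.0144). Spp1, which encodes the secreted phosphoprotein osteopontin, went from 1323 ± 16.8 CPM with to 539 ± 54.5 CPM without asparagine (SD, n = 2 each, adjusted p = 0.00678).

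Genes including these, apart from Spp1, prompted 3 wider lists, tested by camera without the members that had prompted them. YAP and TEAD targets (19 members left, 2 of them called higher) had an adjusted p of 0.3981 over the 3 lists. Hemidesmosome, desmosome and laminin-332 genes (17 left, 3 higher and 1 lower) had 0.2648. Fatty acid synthesis and SREBP1 targets (16 left, median -0.17, 0 called) had 0.05023, just outside the threshold, and 0.3727 as the adjusted p with an estimated correlation. None of the hypotheses that a whole pathway moved was borne out at this threshold. They stay open: a p of 0.05 or more had been set beforehand as counting against them, but the lists had lost called members, and a p that misses the threshold does not show that the lists did not differ.

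The higher epithelial genes were weighed against technical explanations. The size did not rest on library A without asparagine: without it the median was 0.5566, and library B lay above both libraries with asparagine in 21 of 25 members, against 40.1% of all tested genes. The list was also called without library A (camera adjusted p = 2.214e-07). That fit had a single library without asparagine and took its spread from the pair with asparagine. Its call therefore does not show whether the main call rested on library A. The list median lay at percentile 100 of 10000 random lists matched on GC content, transcript length and mean expression, whose middle 95% ran from -0.0975 to 0.167. Genes of the random lists were drawn independently, while the estimated correlation of the epithelial list was 0.19, so that range may be too narrow. An effect of the medium on epithelial genes is a hypothesis that these tests leave standing, found and tested on the same data, while the adjusted p with an estimated correlation was 0.578 and a difference between cultures was not tested.

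For glycolysis and hypoxia genes the test of size came out the other way. Without library A without asparagine the median was -0.1248, 37.2% of its size with all libraries, which is consistent with library A giving most of the size. The list was still called without library A (camera adjusted p = 0.02442). With a single library left in that group, this too does not show whether the main call rested on library A. The main call was lost with an estimated correlation (adjusted p = 0.613). Library B lay below both libraries with asparagine in 18 of 28 members, against 39.5% of all tested genes. The median with all libraries lay at percentile 0 of 10000 matched random lists. These too were drawn gene by gene, while the estimated correlation of the glycolysis list was 0.47. The test of library A was first written as 1 criterion, met by a lost call or by a median under 50% of its size, was reworded after its outcome was known, and is given here as separate tests of size and call; under the first wording the glycolysis list met it and the epithelial list did not.

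A further hypothesis was that transcripts rich in asparagine codons fall without asparagine. Across 11402 protein-coding genes, which are not independent replicates, the Spearman correlation of the share of asparagine codons with the log2 change was -0.06652 for library A and -0.1024 for library B, each against the mean with asparagine. The bound of -0.1 set beforehand for both libraries was not met. The same share correlated at 0.157 with the difference between the libraries with asparagine, which is larger in size than the difference between the groups (-0.0864). The difference between libraries A and B with asparagine also correlated at -0.362 with GC content. The codon share itself correlated at -0.420 with GC content. With GC content and length held fixed by partial correlation, the codon share correlated at -0.0644 with the fold change.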
